A study of Caenorhabditis elegans with 23 samples.

How the data were processed

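Total RNA of young adult C. elegans hermaphrodites was sequenced after removal of ribosomal RNA with RNase H and without poly(A) selection, per the labels' protocols. The series holds 23 samples, 1 per combination of genotype and generation. The 19 libraries of generations up to F8 after repair, or with no repair, were used, and the 4 libraries of generation F20 were not analysed here, so the 3 planned comparisons that need them were not made. The deposited table holds RPKM values from the authors for 100257 windows of 1 kb. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build, the rule for reads that match several places, the read filters and the use of strand are not given in the sources used here. Of its columns, 24 hold values for other samples and were not used in any step. It also holds yes or no marks per window headed GRH, GRTS and misannotated by the authors, with no account of how they were set.

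Depth was estimated from the values. In each library 81.5% to 84.6% of positive values were whole multiples of the value of 1 read, within 0.0051 RPKM. The step gave 458690 to 1152822 reads in the denominator, so 1 read was worth 0.867 to 2.18 RPKM and windows under a few RPKM rest on few reads. The other values were parts of a read, as reads divided between copies of a sequence would be. Because of these, a count test was not run, although one on whole reads had been planned. The share of the total outside the windows was 0.924% to 9.76%.

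The windows could not be placed by a named build. Their numbers on chromosome V end below the last genes of the reference annotation, WBcel235, and the end of V did not match it (below). The table was therefore not taken to be on that build. Numbers on chromosome I also end below its last genes, although 30 of its 30 segments matched, so a short end alone does not show another build. The rule fixed before the data were examined allowed gene names and gene lists only with an annotation of the same build, and coordinates otherwise. This rule was relaxed after a check of the data. Of 202 segments of 500 windows, 199 matched the density of WBcel235 exons best with no shift between window numbers, and the best shift tested in steps of 100 bp was at most 100 bp. The other 3 segments lie on chromosome V from 19500 kb, and windows there are not named. Elsewhere a region carries the names of genes that WBcel235 places at the same window number with an overlap of at least 250 bp. The windows at hrde-1, met-2, set-25 and set-32 fell in the libraries whose labels name those mutations, which is a check on the placing at these loci only. All coordinates are those of the table, counted from 1, and none was converted. A name is therefore uncertain near the edge of a gene, and where genes overlap.

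Windows with a mean of at least 1 RPKM over the 19 libraries were kept, which left 41323. The plan had named 23 libraries for this mean. Tests used limma 3.58.1 (lmFit, and eBayes with trend) in R 4.3.3 on log2(RPKM + 1), and all fold changes are on that scale, which understates changes of low windows. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. As each genotype and generation has 1 library, strains of different background that share the hrde-1 and set-32 state served as replicates, with the other mutations as additive terms. The labels do not say that libraries came from separate cultures, and generations of a repaired line descend from each other, so p-values measure the spread between these libraries. Comparisons within the 10 libraries never repaired and within the 9 early repaired libraries were fitted separately, and comparisons between these sets were fitted over all 19 with a shared spread. Scores were compared with two-sided exact permutation tests. No 2 libraries were identical, with correlations of 0.796 to 0.913 over 171 pairs.

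Called windows of one direction at most 1 kb apart were merged into regions, ranked by the largest absolute log2 fold change of a window, the top window. Named were the 15 highest-ranked regions that rose and the 5 that fell with hrde-1(tm1200), the 10 that rose and the 5 that fell with set-32 in early repaired libraries, the 5 of each direction in every other comparison with calls, the 4 mutated loci, and members of the gene lists past the threshold. Gene values were means of windows that overlap a gene by at least 500 bp, or of its best window, over 11781 genes. The 13 lists written out beforehand, and the histone genes taken by symbol, were tested by counts and by limma's camera with a preset correlation of 0.01 and with an estimated one. The planned list of LTR retrotransposons could not be made from the annotation, and ribosomal and mitochondrial windows were not used here.

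Each fit was tested on simulated reads, with 50 windows changed at each fold. All windows had the same dispersion, 0.0477, a median taken from the early repaired set-32 mutants. No spread between backgrounds was simulated, so recovery in the real libraries may be lower. At 4-fold, 68% were recovered for hrde-1(tm1200) against never mutated over 39966 windows and 84% for set-32 in early repaired libraries over 39954, and 68% for set-32 without repair over 39948. In these simulations 7 and 19 unchanged windows were called, and 12 for set-32 without repair and 14 for early repaired against never mutated set-32(+) libraries. The 19 arose beside 8, 42, 49 and 50 recovered windows of 50 at 2-, 4-, 8- and 16-fold. They are therefore not an estimate of false calls among the 31 real calls for that comparison. For the interaction of hrde-1 with set-32, over 39915 windows, 10% were recovered at 4-fold and 72% at 16-fold. For early repaired against never mutated set-32(+) libraries, over 39962 windows, 34% were recovered at 4-fold. Alternatives were another pseudocount, other filters, rescaling, robust eBayes, other covariates, a replicate block by background, and leaving out libraries, alleles or backgrounds. Thinning of reads, leaving out the 4 libraries with under 600000 reads or over 7% of the total outside the windows, leaving out windows of divided reads, and scores over windows marked GRTS were added after seeing the data. Tables were handled with the R package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.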

Results

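Transcript levels were measured in 19 libraries of young adult C. elegans. HRDE-1 is a germline Argonaute protein that carries small RNAs in the nucleus and is needed for heritable silencing. SET-32 is a SET-domain protein, and MET-2 and SET-25 are methyltransferases of histone H3 lysine 9. In 5 libraries hrde-1 had never been mutated, in 5 it carried the tm1200 mutation, and in 9 the mutation had been repaired and the worms were sampled at generations F3 to F8. The set-32 gene was wild type in 2, 2 and 4 of these and mutated, by the ok1457 or red11 allele, in 3, 3 and 5. The reads per library averaged 796266 in never-mutated and 647019 in tm1200 libraries (two-sided exact permutation p = 0.127). They averaged 1006255 in early repaired set-32 mutants (n = 5) and 759072 in early repaired set-32(+) libraries (n = 4; two-sided exact permutation p = 0.119).

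The mutated loci followed the labels. The window of hrde-1 at III 4175001 to 4176000 stood at 71.1 ± 11.7 RPKM (SD, n = 5) in tm1200 libraries, with a highest value of 87.6, against 224 ± 54.6 (n = 14) elsewhere. In the 9 repaired libraries it stood at 221 ± 43.9. The window of set-25 at III 13288001 was listed at 0 in all 7 met-2 set-25 libraries and at 31.6 ± 9.42 RPKM in the other 12. The window of met-2 at III 8376001 stood at 1.5 ± 1.98 against 41.2 ± 8.03 RPKM in these groups. At set-32, the window at I 9519001 averaged 1.52 RPKM with ok1457 and 4.56 with red11, against 13.1 ± 2.76 (n = 8) in set-32(+) libraries.

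The first comparison asked which windows depend on HRDE-1. A set of near-silent regions was expressed in hrde-1(tm1200). Here and below, the fold change and level of a region are those of its window with the largest change, unless the whole region is named. Windows over F07B7.1 and F07B7.2, at V 8868001 to 8874000, rose most, from 0.258 ± 0.356 RPKM (n = 5) at the top window in never-mutated libraries to 72.5 ± 28.4 (n = 5) in tm1200 (log2 fold change 5.82 ± 0.39 SE, adjusted p = 4.59e-10). A like region at V 8826001 to 8832000, which carries the same gene names, rose by 5.68. The region of eri-6, a helicase gene of the endogenous RNAi pathway, and sosi-1, at I 4460001 to 4465000, rose at its top window, I 4461001, from 1.96 ± 1.35 to 35.5 ± 14.9 RPKM (log2 fold change 3.71 ± 0.41, adjusted p = 3.32e-06). In all, 153 windows in 70 regions rose and 10 windows in 5 regions fell.

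Other high regions were F58H7.5 at IV 913001 to 922000 (1.38 to 76.5 ± 58.9 RPKM at IV 920001), Y23H5A.8 at I 2634001 to 2635000 (0.8 to 55 ± 18.2 RPKM) and W04A8.9 at I 13852001 to 13854000 (1.02 to 52.6 ± 23.8 RPKM at I 13853001). Over the whole F58H7.5 region the tm1200 libraries ran from 3.11 to 125 RPKM. An unnamed region at V 20295001 to 20301000 rose by 5.38 on the log2 scale. W08F4.12 and the F-box gene fbxb-14 at II 582001 rose by 4.46, C38D9.2 at V 17569001 to 17574000 by 4.19 and ZK262.8 and ZK262.9 at V 18439001 to 18442000 by 4.18. The pseudogene WBGene00018648 with F49F1.17 at IV 4128001 to 4136000 rose by 4.02, the pseudogene WBGene00044670 at IV 16316001 to 16318000 by 3.89, and F15D4.5 with F15D4.6 at II 13245001 to 13250000 by 3.69. The mitochondrial import gene timm-17B.2 at IV 8397001 rose by 3.61 ± 0.49 (adjusted p = 7.22e-05) from 23.8 ± 28.7 RPKM. F55B11.6 at IV 14416001 was listed at 0 in the 5 never-mutated libraries and stood at 14.1 ± 7.53 RPKM in tm1200. Exons of W08F4.12 covered 89% of its called window, those of C38D9.2 50% and those of F58H7.5 9%.

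The regions that fell were R10E4.1 at III 4270001 to 4272000 (log2 fold change -2.81, adjusted p = 0.00965), the pseudogenes WBGene00014307 and WBGene00014309 at II 8784001 to 8790000 (-2.51, adjusted p = 6.96e-05), the transthyretin-related gene ttr-6 at X 6596001 (-2.40, adjusted p = 0.0383), F28F8.7 at V 15585001 (-2.27, adjusted p = 0.0225) and hrde-1 itself. At ttr-6 both met-2 set-25 hrde-1(tm1200) libraries were listed at 0 and the other tm1200 libraries stood at 14, 26 and 15.3 RPKM, and the call was lost in 14 alternatives. The call of F28F8.7 was lost in 13, that of R10E4.1 in 8, and those of hrde-1 and the pseudogene region in 3 each. Among the tested windows marked GRTS by the authors, 65 rose over all windows tested and 122 adjusted over the list alone. How that list was chosen is not stated, and it is not independent evidence if these libraries were used. The count of 163 called windows became 14 without the met-2 set-25 libraries, 61 with a pseudocount of 0.1, 28 with a minimum mean of 0.2 RPKM, 20 with no filter and 87 with reads thinned to the lowest depth. Without the met-2 set-25 hrde-1(tm1200) library it was 107.

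Among genes fixed beforehand as nuclear RNAi targets, 2 of 5 rose with hrde-1(tm1200), and 3 adjusted over the list alone. C38D9.2 had a log2 fold change of 3.34 (adjusted p = 0.0034) and F15D4.5 of 3.37 (adjusted p = 0.00542), while bath-45 had 1.49 (adjusted p = 0.156), E01G4.5 0.88 and R03H10.6 -0.08. By camera the list had an adjusted p = 5.46e-09, and an adjusted p = 0.0097 with an estimated correlation. No member was called by limma among 8 nuclear RNAi factors, 16 heterochromatin factors, 34 small RNA pathway genes or 13 P granule genes, nor adjusted over the list alone, where 2316 of all 41323 windows had an unadjusted p under 0.05. Sperm genes (44 tested) had a median log2 fold change of 0.29 and muscle genes (17) of -0.29, with no member called. Their camera adjusted p of 1.34e-06 and 0.00133 became an adjusted p = 0.974 for both with an estimated correlation. The other lists, of oocyte, intestine, neuron, cuticle collagen, heat shock, immune and histone genes, had 0 calls over all genes and adjusted over the list alone.

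Loss of set-32 without repair was compared over the same 10 libraries. F07B7.1, eri-6 and C38D9.2 were not called, and neither was any other window by limma. The set-32 window at I 9519001 was not called either, so this fit missed a difference at the mutated locus. Over all 19 libraries that window stood at 6.94 RPKM or less in set-32 mutants and at 8.28 or more in the others. An unadjusted p under 0.05 was found in 1468 of 41323 windows, where 2066 would be met by chance. The interaction of hrde-1 with set-32 likewise called 0 windows, with 1266 at an unadjusted p under 0.05. Sperm genes had a median log2 fold change of -0.60 with loss of set-32 and no call, and their camera adjusted p = 5.29e-10 became an adjusted p = 0.835 with an estimated correlation. Simulated changes with set-32 were recovered in 68% of cases at 4-fold and 96% at 8-fold, and simulated 4-fold interactions in 10%. Most interactions of that size would therefore be missed. The simulation held no spread between backgrounds, so these shares may be too high. The set-32 and interaction counts were 1 and 3 without wild type, 2 and 1 without set-32(red11), 2 and 2 without met-2 set-25, and 5 and 230 with no filter.

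Without repair, 24 windows were higher and 5 lower with met-2 set-25. Other splits of the libraries gave as many calls (below), so the counts are not credited to the mutation. A region with no annotated gene at I 10204001 to 10219000 held 14 of the raised windows, all of them windows of divided reads, while the other 10 raised windows were not. At I 10217001 it stood at 10.7 ± 6.78 RPKM in all 7 mutant libraries against 0.222 ± 0.203 in the other 12 (log2 fold change in the never-repaired libraries 3.49 ± 0.52, adjusted p = 0.00231). C55C3.3 at IV 5686001 stood at 13.9 ± 3.85 against 0.599 ± 0.81 RPKM (3.38 ± 0.54, adjusted p = 0.00643). F40D4.13 at V 17156001 rose by 3.17, the C-type lectin gene clec-169 at IV 1261001 by 2.97 and mihp-1 at I 13403001 by 2.77. Of these calls, C55C3.3 was lost in 5 alternatives, F40D4.13 in 7, and clec-169 and mihp-1 in 9 each. The lowered regions were met-2 at III 8376001 to 8380000 (-5.45 ± 0.36, adjusted p = 5.07e-10) and set-25. Of the 5 nuclear RNAi targets, 0 rose over all genes and 4 adjusted over the list alone, with a camera adjusted p = 4.4e-05 and an adjusted p = 0.0563 with an estimated correlation. Sperm genes had a median of 0.77 (42 of 44 positive), with 0 calls over all genes and 3 higher adjusted over the list alone, and their camera adjusted p = 2.49e-13 became an adjusted p = 0.434 with an estimated correlation. Muscle genes had a median of 0.37 (17 of 17 positive) and no call, and their adjusted p = 3.84e-06 also became an adjusted p = 0.434. Collagens had 2 members higher adjusted over the list alone and 0 over all genes, with a camera adjusted p = 0.133. The 29 windows became 5 with a pseudocount of 0.1, 2 with a minimum mean of 0.2 RPKM, 8 with no filter, 16 with thinned reads and 17 without windows of divided reads, and 4 without the set-32(ok1457) met-2 set-25 library. They became 13 without wild type, 12 without the hrde-1(tm1200) single mutant, 9 without the set-32(red11) met-2 set-25 hrde-1(tm1200) library, 9 without met-2 set-25 and 7 without met-2 set-25 hrde-1(tm1200).

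The central comparison asked whether silencing returned after repair of hrde-1 with and without set-32. In early repaired worms, a part of the HRDE-1 target regions was highly expressed in set-32 mutants and near the never-mutated level with set-32(+). At F07B7.1 and F07B7.2 the top window stood at 72 ± 10.8 RPKM (n = 5) in set-32 mutants and 1.48 ± 1.47 (n = 4) with set-32(+) (log2 fold change 5.14 ± 0.39, adjusted p = 4.18e-07). At eri-6 and sosi-1 the levels at I 4461001 were 29.2 ± 2.44 and 1.54 ± 1.75 RPKM (3.79 ± 0.43, adjusted p = 0.000169). The phospholipid scramblase gene scrm-4 at I 11681001 to 11683000 stood at 25.9 ± 4.68 against 0.752 ± 0.906 RPKM at I 11681001 (4.34 ± 0.38, adjusted p = 3.69e-06), and over the whole scrm-4 region the set-32(+) libraries ran from 0 to 4.76 RPKM. In all, 31 windows in 16 regions were higher and 0 lower, with 2629 of 41323 windows at an unadjusted p under 0.05 in limma. The set-32 window at I 9519001 was again not called, although it stood at 3.35 ± 2.43 RPKM in set-32 mutants and 12.7 ± 3.46 with set-32(+).

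F15D4.5 at II 13245001 to 13250000 rose by 4.39 ± 0.53 (adjusted p = 0.000314) to 83.2 ± 15.8 RPKM at its top window, and ife-5, a cap-binding translation factor gene at II 12283001, stood at 36.9 ± 3.43 against 2.15 ± 2.49 RPKM. The other F07B7.1 region rose by 5.24, an unnamed region at V 20299001 to 20301000 by 5.90, another at V 20306001 by 3.78, and the pseudogene WBGene00018648 by 3.06, a call lost in 10 alternatives. C38D9.2 was higher in set-32 mutants at V 17570001, by 4.38 ± 0.81 on the log2 scale (adjusted p = 0.0448), a call that was lost in 17 alternatives. Its level with set-32(+) ran from 0 and 0.415 RPKM over the region in F4 and F5 worms to 61.9 and 57.9 in met-2 set-25 worms of F3 and F5. Windows of divided reads are part of these regions, and the count of 31 became 19 without such windows.

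Of the 31 windows, 27 were among the 153 that rose in tm1200, where independent lists would share 0.115. Windows are not separate counts here, as the 31 lie in 16 regions and the 153 in 70. The F07B7.1 regions also had near-equal changes, such as 3.81 at V 8829001 and 3.74 at V 8871001, and may hold the same reads. The libraries of these comparisons are disjoint. Of the 153 windows, 136 had a positive difference, with a median of 1.19 on the log2 scale against 0.031 over all windows. The 4 others, chosen for mention after their values were seen, were at F28F8.7, C27C7.1 and the pseudogene WBGene00003067. The count became 17 with a pseudocount of 0.1, 12 with a minimum mean of 0.2 RPKM, 6 with no filter, 14 with thinned reads, 13 with ok1457 alone and 18 with red11 alone. It became 58 without the set-32(red11) met-2 set-25 library of F5.

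**Figure D1:**
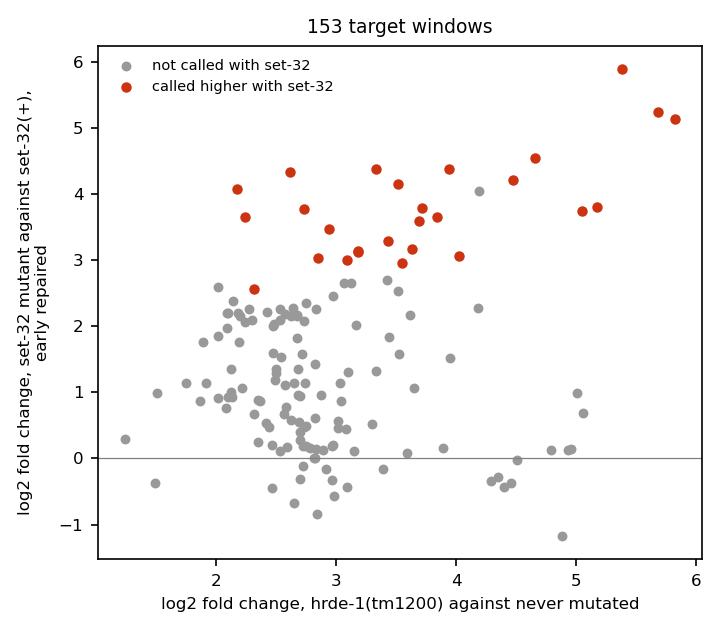
Log2 fold change of log2(RPKM + 1) in hrde-1(tm1200) against never-mutated libraries (x axis) and in set-32 mutant against set-32(+) early repaired libraries (y axis), 1 point per target window. The 27 windows in red were called higher with set-32, and 136 of the 153 lie above 0.

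Fixed lists gave few further calls in this comparison. Among the 5 nuclear RNAi targets F15D4.5 rose (log2 fold change 3.91, adjusted p = 0.0232), and 2 rose adjusted over the list alone, with a camera adjusted p = 0.00213 and an adjusted p = 0.371 with an estimated correlation. Cuticle collagens had a median of -1.10, with 0 calls over all genes and 2 lower adjusted over the list alone. Their camera adjusted p = 5.18e-07 became an adjusted p = 0.641 with an estimated correlation. Sperm genes had a median of -0.50 and no call, and their adjusted p = 0.0259 became an adjusted p = 0.736. Histone genes (71) had a median of -0.18 and no call, and their adjusted p = 0.00026 became an adjusted p = 0.703. Small RNA pathway and P granule genes had medians of 0.14 and 0.16 and no call, and their adjusted p of 0.000705 and 0.0023 became an adjusted p = 0.641 for both. Immune genes had 1 member lower adjusted over the list alone, and 0 over all genes. Sperm genes varied between single libraries from 1.39 to 5.02 and collagens from 1.71 to 5.13 in mean log2 level, and these ranges were not tested against the groups.

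A derepression score put each library between the mean of the never-mutated libraries (0) and of the tm1200 libraries (1) over the 153 target windows. Early repaired set-32 mutants scored 0.546 ± 0.064 (n = 5) and early repaired set-32(+) libraries 0.082 ± 0.135 (n = 4). The difference of 0.464 had a two-sided exact permutation p = 0.00794, and 0.0119 adjusted over 9 tests. That p is the smallest that splits of single libraries allow, and it treats each library as independent. Generations of a repaired line descend from each other, so the independent units are fewer and the p may be too small. Splits by whole lines were not tested. The same limit holds for every exact permutation p that involves repaired libraries. The score of set-32(ok1457) was 0.640 at F5 and 0.554 at F8, and that of set-32(red11) 0.504 at F4 and 0.471 at F5. Early repaired set-32(+) libraries differed from never-mutated ones by 0.082 (exact permutation p = 0.302). Of these 4, the met-2 set-25 libraries scored 0.198 and 0.196 and the others -0.059 and -0.008, a difference of 0.23. Its exact permutation p = 0.333 is the smallest that 6 splits allow, so the test cannot decide. That difference was 0.061 without C38D9.2 and the regions that follow it (correlation of at least 0.9 over the libraries). Set-32 mutants stood 0.454 below tm1200 libraries (-0.454, exact permutation p = 0.00794), on windows picked in those tm1200 libraries, which favours a higher tm1200 value. Without met-2 set-25 libraries the difference was 0.576 (exact permutation p = 0.0667, the smallest that 15 splits allow). Over windows marked GRTS the difference between set-32 mutants and set-32(+) was 0.501 (exact permutation p = 0.00794).

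**Figure D2:**
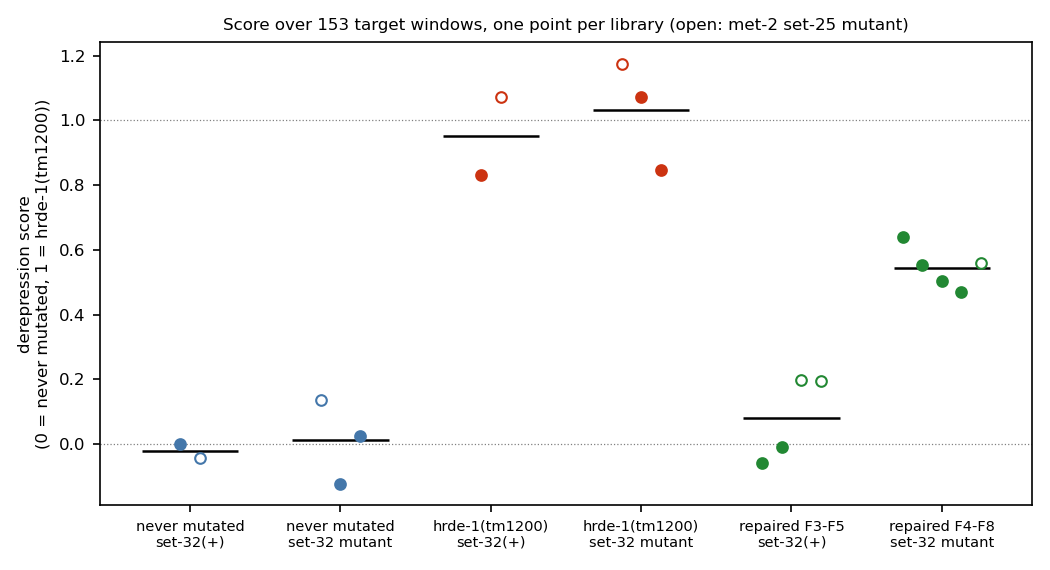
Derepression score (y axis, 0 at the mean of never-mutated and 1 at the mean of tm1200 libraries) for 19 libraries in 6 groups (x axis), 1 point per library, with bars at group means and open points for met-2 set-25 mutants. The 5 early repaired set-32 mutants average 0.546 and the 4 early repaired set-32(+) libraries 0.082.

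The return to silence differed between regions of the set-32 mutants. F07B7.1 held 101% ± 7.7 (SD, n = 5) of its tm1200 rise in RPKM, F15D4.5 98% ± 12.5, eri-6 with sosi-1 70.1% ± 12.1 and ife-5 43.1% ± 7.17. Y23H5A.8 held 6.14% ± 4.69, W04A8.9 2.06% ± 1.35, fbxb-14 0.733% ± 3.37 and F58H7.5 0.387% ± 1.33. Of 47 regions with a tm1200 rise of at least 10 RPKM, 13 held over 75%, 21 under 25% and 13 between. Over all 70 regions, as shares of the rise on the log2 scale, 31 held over 75% and 21 under 25%. The median share was 0.6, against 0.065 with set-32(+). The 31 regions are not separate sources, as they include both F07B7.1 regions, which may hold the same reads. They also include C38D9.2 and the regions that follow it, 13 in all, where 73.9% of positive values were parts of a read. At timm-17B.2 the share was 6.81% ± 21. With set-32(+), sel-2 at III 4607001 also held 124%, and a region with no annotated gene at III 2431001 held 94.4%, against 46.7% ± 55 in set-32 mutants. Other regions were high in only a part of the set-32(+) libraries. C38D9.2 held 168% in the 2 with met-2 set-25 and -11.2% in the 2 without, WBGene00021886 at IV 2904001 held 118% and -13.1%, and fbxa-192 at V 17649001 held 96.3% and 1.82%. F55B11.6 held 16.9% with met-2 set-25 and 78.3% without.

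**Figure D3:**
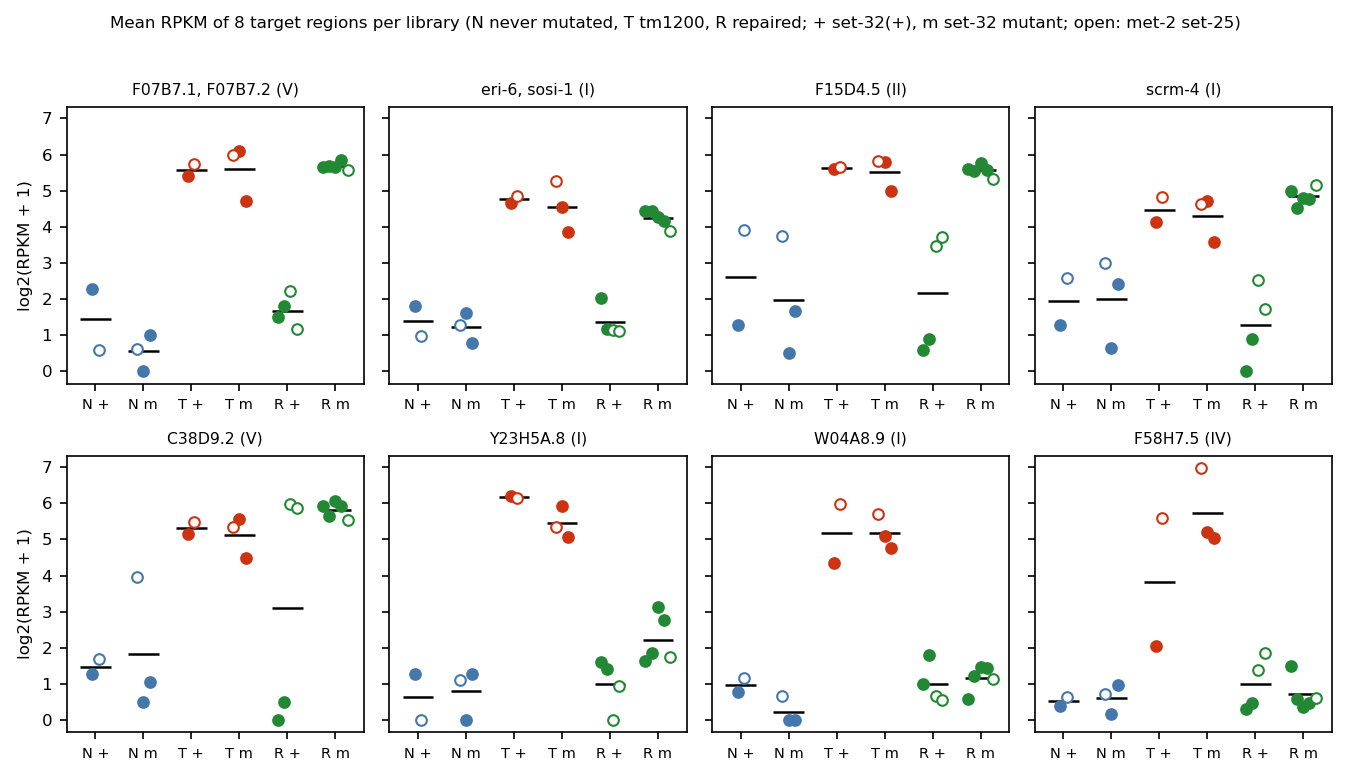
Mean log2(RPKM + 1) (y axis) of 8 target regions in each library, grouped by hrde-1 state and set-32 state (x axis), with bars at group means and open points for met-2 set-25 mutants. F07B7.1, eri-6, F15D4.5, scrm-4 and C38D9.2 stay high in repaired set-32 mutants, and Y23H5A.8, W04A8.9 and F58H7.5 are low there. C38D9.2 is also high with set-32(+) in the repaired met-2 set-25 libraries, at 61.9 RPKM in F3 and 57.9 in F5.

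The early repaired libraries were also set against never-mutated ones over all 19 libraries. In set-32 mutants F07B7.1 and F07B7.2 rose by 6.04 ± 0.40 (adjusted p = 1.58e-10) at V 8829001, C38D9.2 by 4.85 ± 0.78 (adjusted p = 0.00203) and F15D4.5 by 4.19 ± 0.61 (adjusted p = 0.000513), among 53 windows that rose. R10E4.1 (-2.62, adjusted p = 0.00803) and WBGene00014309 (-1.98, adjusted p = 0.00057) made up the 4 windows that fell. The call of R10E4.1 was lost in 7 alternatives, that of C38D9.2 in 6 and that of F15D4.5 in 4. Among the 5 nuclear RNAi targets 1 rose over all genes and 2 adjusted over the list alone, with a camera adjusted p = 1.15e-06 and an adjusted p = 0.00381 with an estimated correlation. Intestine genes had a median of -0.22 in this comparison (2 of 18 positive), with no call, a camera adjusted p = 0.00411 and an adjusted p = 0.0356 with an estimated correlation. Their median was -0.27 after repair with set-32(+) and 0.056 for the difference of repair effects, with a camera adjusted p of 0.47 and 0.412. Muscle, collagen, histone, neuron, oocyte and small RNA pathway genes had a camera adjusted p under 0.05, which became an adjusted p = 0.543 for each with an estimated correlation. With set-32(+) limma called 0 windows, with 2463 at an unadjusted p under 0.05, and simulated 4-fold changes were recovered in 34% of cases. The test of the difference between these repair effects called 12 windows, all higher in set-32 mutants, among them F07B7.1 (5.70 ± 0.71, adjusted p = 9.96e-05), F15D4.5 (5.27 ± 0.95, adjusted p = 0.0226, a call lost in 11 alternatives), eri-6 with sosi-1 (4.64 ± 0.74, adjusted p = 0.00435) and V 20299001 (5.83). The 57 windows of set-32 mutants became 15 with a pseudocount of 0.1, 29 with no filter, 15 with ok1457 alone, 11 with red11 alone, 32 with thinned reads and 25 without windows of divided reads, and 23 to 35 without any single set-32 library of these groups other than the repaired red11 met-2 set-25 one, without which they were 51. The set-32(+) count was 6 without met-2 set-25, 3 without wild type and 38 with no filter, and the 12 windows became 3 with a pseudocount of 0.1, 38 with no filter and 6 without windows of divided reads.

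In early repaired libraries 2 windows were higher and 9 lower with met-2 set-25. Other splits of these libraries gave as many calls (below), so the counts are not credited to the mutation. C55C3.3 rose by 3.48 ± 0.54 (adjusted p = 0.0189), and dod-23 at II 8398001 by 1.71 ± 0.26 (adjusted p = 0.0161), with 112 ± 29.4 RPKM (n = 3) against 33.1 ± 9.03 (n = 6). The noncoding genes K07C10.3 and K07C10.8 at II 11167001 stood at 7.86 ± 7.7 against 253 ± 51 RPKM (-5.39 ± 0.33, adjusted p = 5.79e-08). The transthyretin-related gene ttr-6 was listed at 0 in the 3 mutant libraries and at 20.4 ± 5.66 RPKM in the other 6, and semo-1 at IV 14055001 to 14057000 fell by 2.9 (-2.90, adjusted p = 0.0353). The call of semo-1 was lost in 13 alternatives and those of C55C3.3 and dod-23 in 9 each. The other lowered regions were met-2 and set-25. Of the 5 nuclear RNAi targets 0 rose over all genes and 4 adjusted over the list alone, with a camera adjusted p = 1.86e-06 and an adjusted p = 0.0729 with an estimated correlation. Histone genes had a median of 0.34 (67 of 71 positive), muscle genes of -0.46 (0 of 17 positive) and sperm genes of -1.0, with no call. Their camera adjusted p of 1e-19, 1.82e-06 and 1.3e-08 became an adjusted p of 0.728, 0.84 and 0.851 with an estimated correlation. The 11 windows became 7 without the repaired F5 library with no other mutation, 7 without the met-2 set-25 F3 library, 55 without the set-32(red11) met-2 set-25 library, 5 with a minimum mean of 0.2 RPKM, 7 with a pseudocount of 0.1 or thinned reads, and 100 with no filter.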

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

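Tests of unrestored hrde-1, of mixed worms, of strain variants against loss of HRDE-1, and of met-2 set-25 regions in further libraries were chosen after the results were seen. Single libraries were far from their group in 7 of 54 sets of values, where 2.7 are met by chance, but in 5 of the 7 the value is under 2 reads with the others at 0, which always meets the test and shows nothing about a library. At F07B7.1 (V 8872001) the set-32(red11) F5 library stood at 91.1 RPKM, against 65.1 to 69.8 in the other early repaired set-32 mutants. In early repaired set-32(+) worms, met-2 set-25 F3 stood at 1.79 RPKM at V 20299001 and 1.19 at V 20306001, F5 worms at 1.66 at WBGene00018648, and met-2 set-25 F5 at 0.91 at F15D4.5 (II 13249001), with 0 in the others. Among early repaired set-32 mutants, ok1457 F8 stood at 0.88 RPKM at WBGene00044670 with 0 in the others, and the red11 met-2 set-25 library was listed at 0 for ttr-6 against 15.6 to 28. The early repair effect differed between set-32 mutants and set-32(+) at 12 windows, by limma's test of the difference.

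Splits of the libraries were counted, the real one included, for each comparison with at least 3 libraries a side. Generations of a repaired line were split as separate libraries, although they descend from each other, and splits by whole lines were not tested. For hrde-1(tm1200) the real split was the only 1 of 100 that reached 163 windows, with a highest other of 130, so chance was excluded. For early repaired against never-mutated set-32 mutants it was the only 1 of 56 that reached 57, with a highest other of 9. That also argues against chance. For set-32 in early repaired libraries 3 of 100 reached 31, the real one among them, which argues against chance. The highest other, of 336, set hrde-1(+R) F4 and all 3 met-2 set-25 libraries against the rest, so that with met-2 set-25 as a term it rests on hrde-1(+R) F4, and its cause was not tested. For set-32 without repair the real count was 0, met by all 100 splits, with a highest other of 25.

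For met-2 set-25 the count of windows did not argue against chance, without repair (7 of 100 splits with the real one, real 29, highest other 323) or after repair (5 of 84, real 11, highest other 201). The called regions outside met-2 and set-25 were followed in the libraries of the other repair state, without windows of divided reads. Of 10 called without repair, 2 separated all mutant from all other early repaired libraries, but the highest other of 84 splits gave 3, and of 5 called after repair 1 separated the never-repaired libraries, with a highest other of 1. Chance therefore stays open for these sets of regions, while C55C3.3 was called in both sets of libraries, although the calls were lost in 5 and 9 alternatives. After repair II 11167001 and ttr-6 lay far below the libraries without met-2 set-25 (at most 16.7 against 195 RPKM or more, and 0 against 15.6 or more), but met-2 set-25 alone was argued against as the cause, since 3 of 4 never-repaired libraries with the mutation stood at 183 to 232 RPKM at II 11167001, and the 2 without tm1200 at 32.2 and 40.2 at ttr-6.

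Target regions stood above the never-mutated level in early repaired set-32 mutants. A difference in depth was argued against by a score difference of 0.447 with reads thinned to the lowest depth. An unrestored hrde-1 or a wrong label was argued against by its window, at 179 RPKM or more in these 5 libraries and at most 87.6 in tm1200. A mixture of worms with all regions silenced and worms with none silenced would give every region a like share. Shares differed between regions by more than the residual spread of regions and libraries (F ratio 10.3). Each region has 1 tm1200 rise for all libraries, so error in that rise adds to the ratio, which alone cannot decide. At W04A8.9 the set-32 mutants stood at 1.74 RPKM or less, against 19.3 or more in tm1200. At F07B7.1 (V 8868001) they stood at 46.2 or more, against 25.3 to 68. Such unlike shares argue against that mixture for these 2 regions. Worms silenced region by region could give unequal shares, so the test cannot decide on that kind of mixture. Regions were compared within set-32 mutants only, so a dependence on SET-32 that differs between regions was not tested.

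Regions that follow C38D9.2 were chosen by a correlation of at least 0.9 with it over the 19 libraries. A like profile is therefore partly fixed by the choice. Of 12 such regions, 11 were high with C38D9.2 in early repaired met-2 set-25 worms with set-32(+). F15D4.5 stood at 10.1 and 12.1 RPKM there and at 14.1 and 12.5 in never-mutated met-2 set-25 libraries. A depth difference was argued against, as the log2 difference from the repaired set-32(+) libraries without met-2 set-25 was 3.08 with thinned reads. Reads shared between copies could make 1 source appear as many regions, since 73.9% of positive values in these windows were parts of a read, against 28.3% in other targets. At C38D9.2 itself that share was 14.8%, so a rise of this locus stays open, with met-2 set-25 as an untested biological explanation in 2 libraries. None of these windows was called for met-2 set-25 by limma in early repaired libraries. That fit cannot decide this, because it gives met-2 set-25 the same effect with and without set-32. The set-32 mutants stood at 45.3 to 65.8 RPKM at C38D9.2, with or without met-2 set-25.

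R10E4.1 and the pseudogene region at II 8784001 were low in tm1200 libraries and stayed low after repair. The 9 repaired libraries recovered 8.19% of the log2 distance to never-mutated libraries, which argues against loss of HRDE-1 at sampling. Against never-mutated libraries the exact permutation p was 5e-04, the smallest of 2002 splits. The windows, like that of ttr-6, were picked against these same never-mutated libraries. That choice favours a small p, which is therefore not independent support. A variant or heritable state carried by the tm1200 lines may account for the low levels, and these cannot be separated here. R10E4.1 (III 4270001) lies near hrde-1 (III 4175001). At ttr-6, also lower in tm1200, 16% was recovered (exact permutation p = 0.0325 against never-mutated), with 0 in all 5 tm1200 and repaired met-2 set-25 libraries. F28F8.7 and hrde-1 together recovered 94.6%, with 92% at F28F8.7 and 98.2% at hrde-1. The return of hrde-1 follows from its repair and is no evidence on other loci. F28F8.7 is 1 window, at 0.808 RPKM in tm1200 and 6.5 in repaired libraries, as dependence on hrde-1 at sampling would give. These groups of regions were formed after the results were seen, with ttr-6 left out of both, so the pooled percentages are not independent support.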

How the results depend on the processing

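Thinning, doubtful libraries, divided reads and GRTS scores were tests chosen after the results were seen. The score difference of 0.464 kept its direction in all alternatives run, from 0.391 to 0.693. It lost its threshold when met-2 set-25 libraries were left out (0.576, exact permutation p = 0.0667, the smallest 15 splits allow), because fewer libraries remained. No score could be made from targets called in set-32(+) libraries, where 0 windows passed. With a pseudocount of 0.1 called windows were 61 for hrde-1(tm1200), 5 and 7 for met-2 set-25 before and after repair, 17 for set-32 after repair, 15 for set-32 mutants after repair against never mutated, and 3 for the difference of repair effects. With a minimum mean of 0.2 RPKM they were 28, 2, 5 and 12 for the first 4 of these. With no filter they were 20 for hrde-1(tm1200), 5 for set-32 and 230 for the interaction without repair, 8 and 100 for met-2 set-25, 6 for set-32 after repair, 38 for set-32(+) and 29 for set-32 mutants against never mutated, and 38 for the difference. With thinned reads they were 87 for hrde-1(tm1200), 16 and 7 for met-2 set-25, 14 for set-32 after repair and 32 for set-32 mutants against never mutated. Without windows of divided reads they were 2 for set-32 and 17 for met-2 set-25 without repair, 19 for set-32 after repair, 25 for set-32 mutants against never mutated and 6 for the difference. Leaving out met-2 set-25 libraries gave 14 for hrde-1(tm1200), with fewer libraries. For ok1457 and red11 alone, counts were 13 and 18 for set-32 after repair and 15 and 11 against never mutated, with fewer libraries, and without doubtful libraries the latter was 37. For the other settings the cause was not tested. Without single libraries the range was 107 to 171 for hrde-1(tm1200), lowest without met-2 set-25 hrde-1(tm1200); 0 to 2 for set-32 and 0 to 3 for the interaction without repair; 4 to 32 for met-2 set-25 without repair, lowest without set-32(ok1457) met-2 set-25; 23 to 58 for set-32 and 7 to 55 for met-2 set-25 after repair, both highest without set-32(red11) met-2 set-25. It was 0 to 6 for set-32(+) against never mutated, highest without met-2 set-25, 23 to 51 for set-32 mutants, 8 to 17 for the difference, and 0.417 to 0.503 for the score. The replicate block by background gave 184 for hrde-1(tm1200), all of the 163 among them. Over 1243 values of 56 named regions, 1035 kept their side of the threshold, 208 lost it and 0 reversed. Windows under a few RPKM rest on few reads, which limits low regions.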

Other observations

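The values in this part were chosen after the results were seen, and the differences between generations or lines were not tested. K07C10.3 with K07C10.8 and semo-1 were low in early repaired met-2 set-25 libraries but not in all met-2 set-25 libraries. At II 11167001 the never-repaired met-2 set-25 libraries stood at 220, 183 and 232 RPKM, and at 3.15 in set-32(red11) met-2 set-25 hrde-1(tm1200), against 16.7, 4.56 and 2.37 in the early repaired ones. At X 6596001, ttr-6 stood at 32.2 and 40.2 RPKM in the 2 met-2 set-25 libraries without hrde-1 mutation, and was listed at 0 in the 2 with tm1200 and in the 3 early repaired ones. At V 17156001, F40D4.13 ranged from 1.19 to 106 RPKM over the 7 met-2 set-25 libraries and from 0 to 88 over the other 12.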
